A study of Homo sapiens with 12 samples.

How the data were processed

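The study measured poly(A)-selected RNA by stranded sequencing in HEK293 Flp-In-TReX cells, a human embryonic kidney line. Cells were transfected with small interfering RNA against MKRN2, a makorin-family protein with RING and zinc finger domains, or served as controls. Per the labels, independent transfections were made, cells were fractionated with detergent, and RNA came from total, nuclear and cytoplasmic preparations. The 2 conditions and 3 fractions form 6 groups of 2 libraries each, 12 in all.

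The deposited file is a table of FPKM (fragments per kilobase of transcript, nominally scaled to the mapped fragments) made by the authors for 27835 gene symbols in 12 libraries. Per the labels, Salmon, DESeq2 and the human genome build hg38 were used, but neither their versions and roles nor the annotation is stated. The sums of FPKM differ between the libraries, from 491769 to 1148830, and how the values were scaled is not described. Sample titles number the replicates 1 and 2, whereas the columns of the table carry the numbers 2 and 3. Columns were therefore assigned to the 6 groups only, and a library is named here by its group and the number in the table, without a claim about which title it belongs to.

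Gene symbols were matched to a RefSeq gene table for hg38, 25802 by current symbol and 1094 by a synonym of a single gene, with 939 unmatched. The biotype in that table, together with symbol patterns for microRNAs, small nucleolar RNAs (snoRNAs), small Cajal body RNAs, SNAR RNAs and similar classes, defined small RNAs. How far poly(A) selection kept small RNAs, replication-dependent histone mRNAs or ribosomal RNA precursors was not measured. Their values here are levels in the selected RNA, which need not be those in the cell. Transcript length and GC content came from the longest GENCODE v29 transcript of each symbol and were available for 96.8% of the genes tested.

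Genes with at least 1 FPKM in at least 2 libraries were kept, which left 13628, of which 576 were small RNAs. The values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, in a single fit of 6 group means with moderated variances that follow a trend with level. All groups therefore shared 1 estimate of the spread. The 6 comparisons were knockdown against control in total, nuclear and cytoplasmic RNA, the change in the nuclear to cytoplasmic ratio (the difference of differences), and nucleus against cytoplasm in control and in knockdown cells. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are given with their standard error from limma, and FPKM means with their standard deviation (SD) over 2 libraries.

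Gene lists were tested with camera, part of limma, with a preset correlation of 0.01 between genes and adjustment over the 22 lists that had at least 3 measured members. The lists were the makorin family, GLE1 and mRNA export factors, nucleoporins, nuclear-retained RNAs, detained-intron kinase and splicing factor mRNAs, snoRNA host genes, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits, mitochondrially encoded genes (too few measured members), endoplasmic reticulum (ER) protein folding and translocation, cholesterol synthesis and uptake, replication-dependent histones, genes of the G1/S and G2/M phases, immediate early genes, p53 targets, the integrated stress response with ATF4, interferon response, heat shock proteins, glycolysis and hypoxia, proteasome subunits, transcription factors of eye development, and markers of other cell types. Counts "adjusted over the list alone" use adjustment within a list. Each list was also tested with a correlation estimated from the data and with fry, a rotation test.

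A nuclear weight was computed for each condition and table number, as the share of the nuclear profile that, mixed with the cytoplasmic profile, came closest to the total profile on the log2 scale. It was compared between conditions with an exact two-sided permutation test, whose smallest possible p with 2 values per condition is 0.333.

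Genes were named by a rule. MKRN2, its paralog MKRN1 and GLE1 were named in every knockdown comparison. In each comparison, up to 12 genes per direction were named among those that passed, had libraries that did not overlap between the compared groups, carried an assigned symbol and reached a mean of 5 FPKM in the higher group, starting from the largest log2 difference. The members of a list with the smallest p were named with it. Some genes that the rule names are left out here. Genes named outside the rule are marked as chosen after their values were seen. The comparisons, lists, rule and most alternatives were fixed before the data were examined.

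The table gives no read counts. Low values of a library lie on multiples of a smallest step, which is the FPKM of 1 read of a gene. The inverse ratio of these steps gave relative scaling factors of 55.9% to 116% of that of the library control total 2. Such a factor equals relative depth only if the values were scaled to read totals, which is not described. Whole reads could be recovered for 5583 genes, 41.0% of those kept, with sums of 8091540 to 12682080 reads in a library. This recovery was tested on simulated data, where 945 of 945 genes with whole reads were recovered and 0 of 942 with fractional reads were called whole. Reads were recovered up to a common factor of a gene, so its true reads may be a multiple. The simulated genes counted were above 0 in more libraries than most genes called in the knockdown comparisons. The check therefore does not cover most of those. No bound was computed for genes listed at 0, and no fold is given against a group listed at 0.

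The test was checked on simulated data with the spread of the deposited values. At a true change of 4-fold it recovered 75.8% of the changed genes with a mean of at least 5 FPKM in total RNA, 69.7% in nuclear RNA, 66.7% in cytoplasmic RNA and 39.4% for the change in ratio. At 2-fold the shares were 17.9%, 19.4%, 14.9% and 1.49%. Of the unchanged simulated genes 1, 7, 2 and 2 were called, and 4.78% to 5.28% had an unadjusted p under 0.05 in limma. In the deposited values 61, 91, 106 and 80 of 13628 genes had one, a far smaller share. The p-values of these comparisons therefore ran high, and few passing genes do not show that little changed. The simulated spread was drawn independently for each library, whereas libraries of 1 number deviated together in the data (r = 0.625 in nuclei and 0.503 in cytoplasm, across genes). The main fit counts such shared deviation as spread. The recovered shares therefore need not hold for these data.

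The alternatives fixed at that time were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 FPKM, scaling by the median of ratios, quantile normalization, removal of mitochondrially encoded genes with rescaling, a fit on the compared groups alone, robust variance estimation, the table number as a block, and leaving out each library in turn. Median-of-ratios factors of the deposited values were 0.985 to 1.04, so scaling by them could change little. The removal of mitochondrial genes also rescaled every library to the same FPKM sum. The mitochondrial RNAs RNR1 and RNR2 measured 7649 and 14375 FPKM in control cytoplasmic 2, of a sum of 1148830 FPKM. Shifts of all genes between nucleus and cytoplasm under that alternative therefore come mostly from the rescaling. Alternatives added after the data were seen left out small RNAs, used the number as a block within each fraction, ran limma's voom on the recovered reads, left out both nuclear libraries numbered 2, or removed the trend with GC content and length. No gene or library was left out of the main comparisons beyond the filter on low values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.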

Results

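Poly(A)-selected RNA was sequenced from HEK293 cells with and without knockdown of MKRN2, from whole cells and from nuclear and cytoplasmic fractions, with 2 libraries in each of the 6 groups. The relative scaling factor ranged from 55.9% of that of control total 2 in control cytoplasmic 2 to 116% in MKRN2 knockdown nuclear 3. It need not be the relative depth. Recovered reads were 8091540 in control cytoplasmic 2 and 11244594 in control total 2. Library read totals were not used here. Between 12303 and 12945 genes reached 1 FPKM in a library. The first principal component of the 12 libraries held 51.6% of the variance and set the cytoplasmic libraries apart from the total ones. The median SD between the libraries of a group was 0.11 on the log2 scale in total RNA, 0.26 in nuclear RNA and 0.29 in cytoplasmic RNA.

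Transcripts with a known location were compared first. The mitochondrial ribosomal RNAs RNR1 and RNR2, which are made and kept inside mitochondria, were higher in every cytoplasmic library than in every nuclear one. RNR2 measured 750 and 1745 FPKM in control nuclei against 14375 and 7775 FPKM in control cytoplasm. MALAT1, a long noncoding RNA of nuclear speckles, measured 1.91 and 8.57 FPKM in control nuclei and 1.54 and 3.73 FPKM in control cytoplasm. NEAT1, the RNA scaffold of paraspeckles, measured 5.61 and 13.6 FPKM in control nuclei and 4.92 and 8.85 FPKM in control cytoplasm. For MALAT1 the log2 difference between nucleus and cytoplasm was 0.61 ± 0.59 (SE, 2 libraries per group) and for NEAT1 it was 0.36 ± 0.51, and neither passed in limma (adjusted p = 0.625 and 0.756). Each was higher in the nuclear than in the cytoplasmic library of the same number in all 4 pairs. The list of nuclear-retained RNAs, with 7 measured members, did not pass either, at a median of 0.36 and an adjusted p of 0.875.

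**Figure D1:**
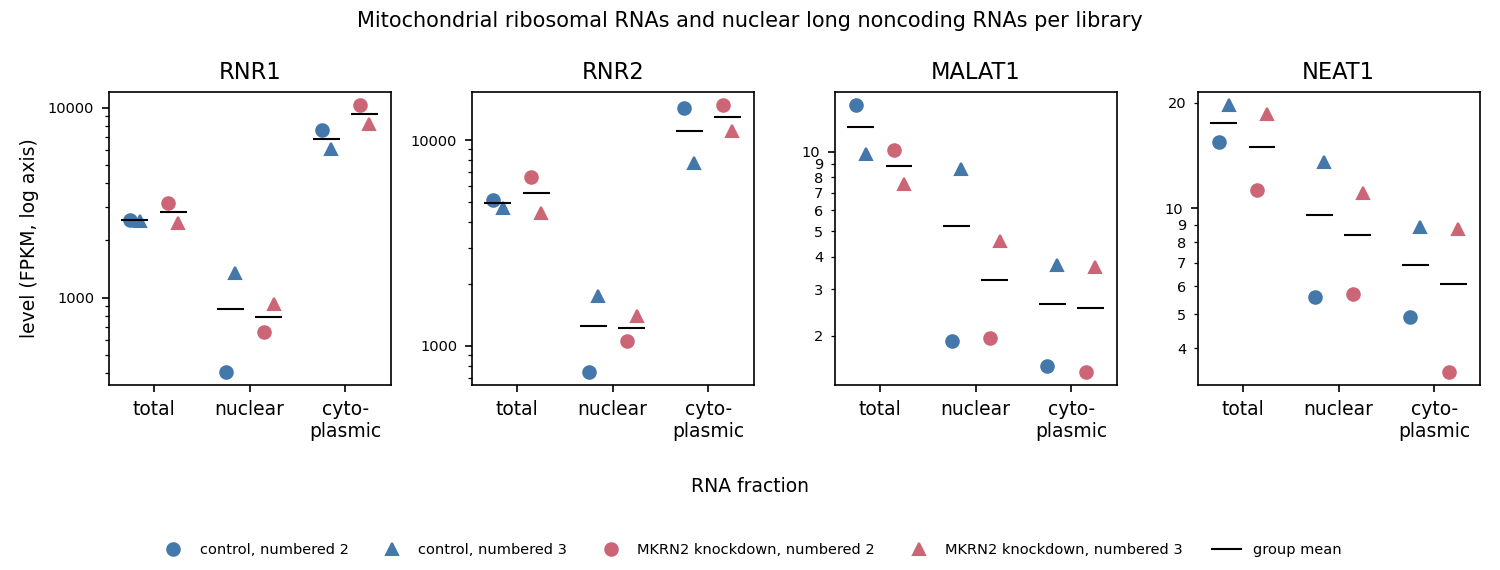
Level of RNR1, RNR2, MALAT1 and NEAT1 (FPKM, log axis) in each of the 12 libraries by RNA fraction, with circles for libraries numbered 2, triangles for libraries numbered 3 and bars for group means. RNR1 and RNR2 are higher in every cytoplasmic library than in every nuclear one, while the nuclear and cytoplasmic values of MALAT1 and NEAT1 overlap.

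The first question was how far the transfections lowered MKRN2. In total RNA, MKRN2 (chromosome 3, 12557087 to 12583713, hg38) measured 21.9 ± 1.17 FPKM (SD, n = 2) in control and 13.3 ± 0.554 FPKM in knockdown cells. In nuclear RNA the means were 21.2 ± 1.63 and 13.9 ± 1.94 FPKM, and in cytoplasmic RNA 27.7 ± 0.530 and 12.98 ± 3.50 FPKM. The log2 differences were -0.67 ± 0.21 (SE) in total, -0.58 ± 0.21 in nuclear and -1.06 ± 0.21 in cytoplasmic RNA. Both knockdown libraries lay below both control libraries in each fraction. MKRN1, a paralog, differed by -0.03 ± 0.21, -0.06 ± 0.21 and -0.04 ± 0.21 in the same order, with a sign in nuclear RNA that turned to 0.01 under quantile normalization and to 0.05 with mitochondrial genes removed. GLE1, an mRNA export factor of the nuclear pore, differed by -0.06 ± 0.25, -0.11 ± 0.25 and -0.06 ± 0.25, and with mitochondrial genes removed the nuclear value was 0.01. None of these 3 genes passed over all 13628 genes in limma (adjusted p = 1 each), and adjusted over the list alone 1 of the 3 makorin genes, MKRN2, passed in total and in cytoplasmic RNA. With 2 libraries per group, an exact permutation test of a single gene cannot give a p under 0.333.

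**Figure D2:**
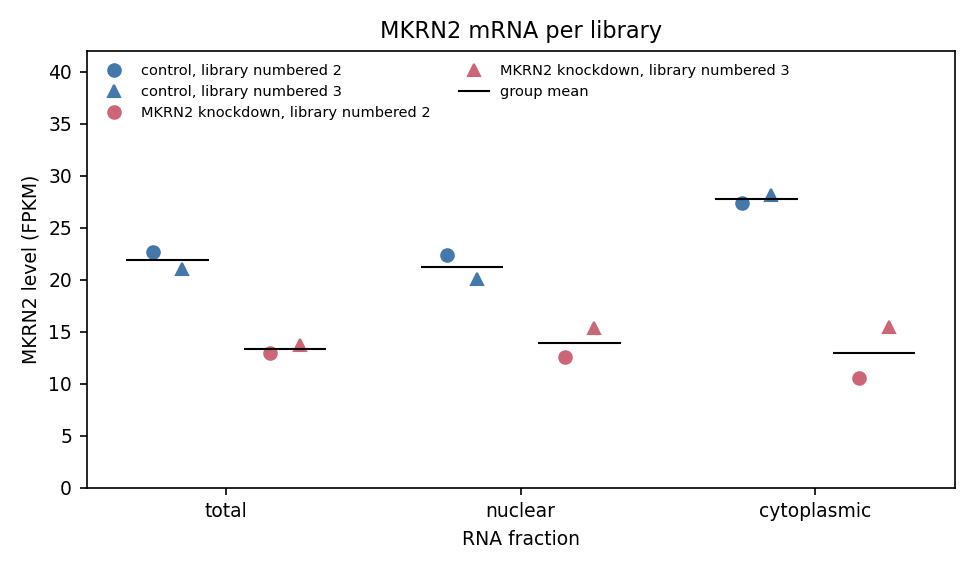
MKRN2 level (FPKM) in each of the 12 libraries by RNA fraction, with circles for libraries numbered 2, triangles for libraries numbered 3 and bars for group means. Control libraries lie between 20.04 and 28.1 FPKM and knockdown libraries between 10.5 and 15.5 FPKM.

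The comparison of total RNA asked which transcripts changed in whole cells after knockdown. Of 13628 genes, 3 rose and 5 fell, and 7 of these 8 were small RNAs. SNORD12B, a C/D box snoRNA, was listed at 0 in both control total libraries and measured 44.5 and 30.01 FPKM in knockdown. In the control fractions, however, SNORD12B measured 16.1 and 59.1 FPKM (nuclear) and 27.3 and 57.8 FPKM (cytoplasmic). SNORA46, an H/ACA snoRNA, was listed at 0 in both control libraries and measured 10.5 and 8.24 FPKM in knockdown, and the microRNA MIR6132 measured 6.15 and 4.84 FPKM against 0 in both. The microRNA genes MIR4477B (5.69 and 11.1 FPKM in control), MIR3671 (10.998 and 5.37), MIR4728 (6.06 and 5.92) and MIR3195 (5.61 and 5.48) fell to a listed level of 0 in both knockdown libraries. The antisense RNA CELSR3-AS1, which falls outside the naming rule and was chosen after its values were seen, went from 2.40 and 2.35 FPKM to 0 in both. The call of SNORD12B (adjusted p = 0.00810 in limma) ended without control total 2 (0.0774), control total 3 (0.0913) or MKRN2 knockdown total 2 (0.122). Without MKRN2 knockdown total 3 the number of genes rose to 15, and it was 16 in a fit on the total libraries alone, 5 at pseudocount 0.1 and 1 with the filter at 5 FPKM. It was also 1 without small RNAs and 1 with voom on recovered reads, both chosen after the data were seen.

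Among the gene lists in total RNA, the 72 nuclear-encoded subunits of the respiratory chain were lower in 62 members, with a median log2 difference of -0.07 (camera adjusted p = 0.00246, and adjusted p = 0.932 with an estimated correlation). NDUFB6 and NDUFC1, both of complex I, differed by -0.37 ± 0.26 and -0.23 ± 0.26. The 32 replication-dependent histone genes, which package new DNA in S phase, were lower in 21 members with a median of -0.05 (adjusted p = 0.00521, and adjusted p = 0.932 with an estimated correlation), for example HIST1H2AG at -0.56 ± 0.30 and HIST1H4E at -0.46 ± 0.29. The share of histone mRNA that poly(A) selection kept was not measured. All 3 makorin genes were lower (median -0.11, adjusted p = 0.00246, and adjusted p = 0.372 with an estimated correlation), of which MKRN2 is the knockdown target itself. Within the respiratory and histone lists 0 members passed in limma, over all genes or adjusted over the list alone, against 61 genes of all kinds at an unadjusted p under 0.05. All 3 list calls ended without MKRN2 knockdown total 3 (adjusted p = 0.430 for the respiratory chain, 0.187 for histones and 0.167 for makorins), and that of the respiratory chain also without control total 2 (0.959). The makorin call ended with no filter on low values (0.253), and the histone call ended when the trend with GC content and length was removed (0.153).

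In nuclear RNA, 6 genes rose and 4 fell after knockdown, and all 10 were small RNAs. SNAR-C4, a small noncoding RNA transcribed by RNA polymerase III, measured 58.4 and 96.5 FPKM in control nuclei and was listed at 0 in both knockdown nuclei and in all total and cytoplasmic libraries. The microRNA genes MIR6132 (7.79 and 11.4 FPKM in control) and MIR639 (8.27 and 6.07) and the snoRNA SNORD150 (9.26 and 6.80) also fell to a listed level of 0. The snoRNAs SNORA29 (10.3 and 10.4 FPKM in knockdown) and SNORA80E (5.37 and 7.26) and the microRNA genes MIR4477B (7.24 and 9.79) and MIR3621 (7.10 and 4.80) rose from 0 in both control nuclei. SNORA49 and MIR1289-1, which are below the level of the naming rule and were chosen after their values were seen, rose from 0 to 5.26 and 3.55 FPKM and to 5.00 and 3.38 FPKM. MIR6132 and MIR4477B moved the opposite way in total RNA. All 10 calls held whichever of the 4 nuclear libraries was left out, while the number of genes rose to 18 without control nuclear 3 and to 20 without MKRN2 knockdown nuclear 3. With small RNAs left out, 0 genes passed in limma (60 at an unadjusted p under 0.05), and 0 passed with voom on recovered reads (64). In a fit on the 4 nuclear libraries alone 0 passed as well (87), and with the filter at 5 FPKM 3 passed. Nuclear libraries of 1 number deviated together (r = 0.625 across genes). Small RNAs were also left out with a term for the number in each fraction, chosen after the data were seen. Then 0 genes passed and 2033 had an unadjusted p under 0.05 in limma, against 60 without that term. The main fit counts the shared deviation as spread, so its few calls do not exclude changes of messenger RNAs.

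The lists lower in knockdown nuclei were the respiratory chain (60 of 72 members, median -0.12), glycolysis and hypoxia (22 of 28, median -0.25) and immediate early genes (22 of 28, median -0.13). Their camera adjusted p were 0.0335, 0.0335 and 0.0387, and the adjusted p was 0.910 for each with an estimated correlation. Named members were COX5B of the respiratory chain at -0.39 ± 0.36 and, against its list, NDUFA5 at 0.31 ± 0.25, the neuronal enolase ENO2 at -0.47 ± 0.29, the glucose transporter SLC2A3 at -0.31 ± 0.19, and the early response genes NR4A1 at -0.47 ± 0.25 and DUSP4 at -0.30 ± 0.18. In none of the 3 lists did a member pass in limma, over all genes or adjusted over the list alone, against 91 genes at an unadjusted p under 0.05. Across 12695 genes the nuclear difference fell with the GC content of the transcript (Spearman's rho = -0.697, over genes, which are not independent replicates), and with that trend removed the adjusted p of the immediate early genes was 0.656. The medians were -0.01, -0.13 and -0.13 under quantile normalization and -0.00382, -0.13 and -0.04 with mitochondrial genes removed. Quantile normalization ended all 3 calls (adjusted p = 0.440 for the respiratory chain, 0.105 for glycolysis and hypoxia and 0.0984 for immediate early genes), as did no filter on low values (0.115, 0.133 and 0.133), and the immediate early call also ended with mitochondrial genes removed (0.225) or with the number as a block (0.0595). The respiratory call ended without control nuclear 3 (0.159) or MKRN2 knockdown nuclear 2 (0.946), the glycolysis call without control nuclear 2 (0.569) and turned without MKRN2 knockdown nuclear 3 (0.814), and the immediate early direction turned without control nuclear 2 (0.614) or MKRN2 knockdown nuclear 3 (0.118). With a term for the number in each fraction, chosen after the data were seen, no omission turned any of the 3 lists. The respiratory call then ended without number 2 (0.651 and 0.653, leaving out the control or the knockdown library), and the immediate early call without number 3 (0.434 each).

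In cytoplasmic RNA, 3 genes rose and 3 fell. The microRNA gene MIR4322 (20.6 and 6.58 FPKM in knockdown) and SCARNA23 (7.55 and 4.82), a guide RNA of Cajal bodies, were listed at 0 in both control libraries. CELSR3-AS1, again chosen after its values were seen, measured 4.19 and 5.35 FPKM against 0 in both. The snoRNAs SNORD26 (10.5 and 13.3 FPKM in control), SNORD150 (10.5 and 6.65) and SNORA80E (7.55 and 4.79) fell to a listed level of 0. The call of SNORD26 (adjusted p = 0.0338 in limma) ended without any 1 of control cytoplasmic 2 (0.203), control cytoplasmic 3 (0.191), MKRN2 knockdown cytoplasmic 2 (0.428) and MKRN2 knockdown cytoplasmic 3 (0.256). That of MIR4322 ended without control cytoplasmic 2 (0.118) or 3 (0.105), and that of SNORA80E without MKRN2 knockdown cytoplasmic 2 (0.0528). In a fit on the 4 cytoplasmic libraries alone 0 genes passed in limma (90 at an unadjusted p under 0.05), and with voom on recovered reads 0 passed (43). With the filter at 5 FPKM 0 passed (57), and without small RNAs 1.

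All 80 cytosolic ribosomal protein mRNAs were higher after knockdown, with a median log2 difference of 0.16 (camera adjusted p = 2.09e-09, and adjusted p = 0.994 with an estimated correlation), for example RPL13A at 0.40 ± 0.32 and RPL4 at 0.22 ± 0.18. Of 31 mRNAs for protein folding and translocation at the ER, 30 were higher with a median of 0.15 (adjusted p = 0.000244, and adjusted p = 0.757 with an estimated correlation), led by the lectin chaperone CANX at 0.50 ± 0.27 and the translocon-associated SSR1 at 0.28 ± 0.21. Among 18 eye development transcription factors 14 were higher, with a median of 0.10 (adjusted p = 0.0134, and adjusted p = 0.994 with an estimated correlation), among them LHX2 at 0.32 ± 0.17 and SOX4 at 0.37 ± 0.28. Of 43 genes of the G2/M phases 41 were lower, with a median of -0.13 (adjusted p = 0.00440, and adjusted p = 0.757 with an estimated correlation), such as the kinesin KIF2C at -0.34 ± 0.34 and the kinetochore gene NUF2 at -0.27 ± 0.30. The makorin list passed as lower (median -0.04, adjusted p = 0.00685, and adjusted p = 0.757 with an estimated correlation). Of its members the knockdown target MKRN2 stood at -1.06, MKRN1 at -0.04 (0.19 without control cytoplasmic 3) and MKRN3 at 0.04 ± 0.20. No member of these lists other than MKRN2 passed, over all genes or adjusted over the list alone, against 106 genes at an unadjusted p under 0.05 in limma. The medians of the ribosomal, ER, eye and G2/M lists were 0.04, 0.11, 0.08 and -0.14 under quantile normalization and 0.09, 0.07, 0.03 and -0.19 with mitochondrial genes removed.

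Each of these cytoplasmic list calls ended or turned without at least 1 of the 4 libraries. Without control cytoplasmic 3 the ribosomal protein list was lower instead of higher (adjusted p = 1.05e-06), the G2/M direction turned (0.994), and the calls of the ER list (0.0573), the eye factors (0.115) and the makorins (0.757) ended. Without MKRN2 knockdown cytoplasmic 2 the ribosomal protein direction turned (0.671). Without the same library the ER, makorin and G2/M calls ended (0.228 each). Without control cytoplasmic 2 the calls of the ER list (0.244), the makorins (0.112) and the eye factors (0.584) ended, and that of the eye factors also without MKRN2 knockdown cytoplasmic 3 (0.623) and with no filter on low values (0.0647). The libraries of 1 number deviated together in control and knockdown cytoplasm (r = 0.503 across genes). With a term for the number in each fraction, chosen after the data were seen, the makorin call ended (0.221). Without control cytoplasmic 3 the ribosomal protein direction then turned (0.828) and the G2/M direction held (0.828), neither past the threshold.

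The central question of the design was whether knockdown shifted transcripts between nucleus and cytoplasm. The ratio rose for 6 genes and fell for 5, and 10 of the 11 were small RNAs. SNORA80E was listed at 0 in both control nuclei and measured 7.55 and 4.79 FPKM in control cytoplasm, whereas in knockdown cells it measured 5.37 and 7.26 FPKM in nuclei and 0 in both cytoplasmic libraries. The other 10 were seen in 1 of the 2 fractions. Their change in ratio repeats the difference already given for that fraction. SNORA29, MIR4477B, MIR3621, SNAR-C4, MIR6132 and MIR639 were listed at 0 in all 4 cytoplasmic libraries and SCARNA23 in all 4 nuclear ones. CELSR3-AS1 (0 in the nuclear libraries), SNORA49 and MIR1289-1 (0 in the cytoplasmic ones), chosen after their values were seen, make up the rest of the 11. For MKRN2 itself the log2 change in ratio was 0.49 ± 0.30 (adjusted p = 1 in limma), for MKRN1 -0.03 ± 0.29 and for GLE1 -0.04 ± 0.35. The MKRN1 value was 0.05 under quantile normalization and 0.16 with mitochondrial genes removed, where that of GLE1 was 0.14. The call of SNORA29 ended without any 1 of the 8 libraries other than MKRN2 knockdown nuclear 3, at adjusted p of 0.0515 (control nuclear 3), 0.0634 (control nuclear 2), 0.0648 (MKRN2 knockdown cytoplasmic 3), 0.0694 (control cytoplasmic 2), 0.0738 (MKRN2 knockdown nuclear 2), 0.0745 (control cytoplasmic 3) and 0.0747 (MKRN2 knockdown cytoplasmic 2). That of MIR4477B ended without control nuclear 2 (0.0594), MKRN2 knockdown cytoplasmic 3 (0.0638), control cytoplasmic 2 (0.0694), control cytoplasmic 3 (0.0745) or MKRN2 knockdown cytoplasmic 2 (0.0747), and the number of genes rose to 21 without MKRN2 knockdown nuclear 3. It was 6 at pseudocount 0.1 and 2 with the filter at 5 FPKM. In tests chosen after the data were seen it was 1 without small RNAs and 0 with voom on recovered reads (38 at an unadjusted p under 0.05). No messenger RNA was among the 11, and 2808 genes (20.6%) had ratios that did not overlap between conditions. Chance gives 33.3% for exchangeable libraries, which those of 1 number, deviating together, are not.

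Of the lists, 4 shifted toward the cytoplasm after knockdown and 1 toward the nucleus. Ribosomal protein mRNAs shifted in 73 of 80 members (median -0.25, camera adjusted p = 9.99e-06, and adjusted p = 0.879 with an estimated correlation), for example RPS28 at -0.47 ± 0.54. ER folding and translocation mRNAs shifted in 24 of 31 (median -0.31, adjusted p = 0.00208, and adjusted p = 0.879 with an estimated correlation), with CANX at -0.78 ± 0.39 and the oligosaccharyltransferase subunit RPN1 at -0.48 ± 0.41. The respiratory chain shifted in 60 of 72 (median -0.16, adjusted p = 0.0114, and adjusted p = 0.890 with an estimated correlation), with COX6A1 at -0.51 ± 0.63 and, the other way, NDUFA5 at 0.41 ± 0.36. Immediate early genes shifted in 23 of 28 (median -0.15, adjusted p = 0.0313, and adjusted p = 0.879 with an estimated correlation), with JUND at -0.48 ± 0.43 and CTGF at -0.37 ± 0.38. The G2/M genes had higher ratios in 26 of 43 (median 0.14, adjusted p = 0.0227, and adjusted p = 0.879 with an estimated correlation), with the kinetochore genes NDC80 at 0.56 ± 0.32 and NUF2 at 0.52 ± 0.43. In these 5 lists 0 members passed in limma, over all genes or adjusted over the list alone, against 80 genes at an unadjusted p under 0.05. Removing mitochondrial genes, with every library rescaled to the same FPKM sum, moved the median ratio change of all genes by 0.15. It moved the medians of the respiratory chain and of immediate early genes to 0.03 each. It moved that of ribosomal proteins to -0.06, of ER genes to -0.12 and of G2/M genes to 0.33. Under quantile normalization the medians were -0.05 for ribosomal proteins, -0.16 for ER genes, -0.00985 for the respiratory chain, -0.11 for immediate early genes and 0.25 for G2/M genes. Across 12695 genes the change in ratio fell with GC content (Spearman's rho = -0.689, over genes). With that trend removed the immediate early genes (adjusted p = 0.826) and the G2/M genes (0.131) no longer passed.

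None of these 5 shifts held in every omission of 1 of the 8 nuclear and cytoplasmic libraries. Without control cytoplasmic 3 the ribosomal proteins (adjusted p = 4.01e-06) and the respiratory chain (7.04e-06) shifted the opposite way, toward the nucleus, and the G2/M (0.830) and immediate early (0.534) calls ended. Without MKRN2 knockdown nuclear 2 the calls of ribosomal proteins (0.720), respiratory chain (0.802) and G2/M genes (0.705) ended, and without MKRN2 knockdown cytoplasmic 2 so did those of ribosomal proteins (0.896), ER genes (0.0831), immediate early genes (0.149) and G2/M genes (0.0945), while the respiratory direction turned (0.360). The ER call also ended without control cytoplasmic 2 (0.284) or MKRN2 knockdown nuclear 3 (0.334), the respiratory call without control nuclear 3 (0.0746), the G2/M call without control nuclear 3 (0.201) or MKRN2 knockdown cytoplasmic 3 (0.0822), and the immediate early call without control cytoplasmic 2 (0.214) or MKRN2 knockdown cytoplasmic 3 (0.118), with its direction turned without control nuclear 2 (0.880) or MKRN2 knockdown nuclear 3 (0.287). The libraries of 1 number deviated together in control and knockdown cells (r = 0.625 in nuclei and 0.503 in cytoplasm, across genes). With a term for the number in each fraction, chosen after the data were seen, no omission turned any of the 5 lists. Without control cytoplasmic 3 the ribosomal proteins (0.448) and the respiratory chain (0.736) then kept their direction and lost the call. Quantile normalization ended the ribosomal (0.198) and respiratory (0.435) calls, the filter at 5 FPKM (0.0538) and the removal of mitochondrial genes (0.2) ended the immediate early call, and no filter on low values ended the immediate early (0.136), G2/M (0.0786) and respiratory (0.0786) calls. Leaving out both nuclear libraries numbered 2, a choice made after the data were seen, ended the ribosomal (0.529), G2/M (0.536) and respiratory (0.856) calls.

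The comparison of nucleus and cytoplasm within control cells described where transcripts lay before any knockdown. There 59 genes were higher in the nucleus and 21 in the cytoplasm, 28 of them small RNAs. SNAR-C4 measured 58.4 and 96.5 FPKM in nuclei and was listed at 0 in both cytoplasmic libraries. Among small RNAs measured in both fractions, SCARNA9, a Cajal body RNA, was 4.92 ± 0.42 (SE) higher in nuclei on the log2 scale, at 38.9 and 100.2 FPKM against 1.20 and 1.02 FPKM. SNAR-B1 was 4.80 ± 0.36 higher. Others listed at 0 in both cytoplasmic libraries were the C/D box snoRNAs SNORD38B, SNORD14D, SNORD14C and SNORD77 and the H/ACA snoRNAs SNORA25, SNORA7A, SNORA63B, SNORA3B and SNORA24, of which SNORA63B measured 21.2 and 46.8 FPKM in nuclei. Messenger RNAs higher in the nuclear preparation, each chosen after its values were seen, were the actin-binding scaffold IQGAP1 (3.58 ± 0.32), drebrin DBN1 (3.43 ± 0.40), beta-spectrin SPTBN1 (3.25 ± 0.41), the cytokinesis protein ANLN (3.11 ± 0.29), MACF1 (2.04 ± 0.32), caldesmon CALD1 (2.02 ± 0.29), the nuclear envelope protein SYNE2 (1.88 ± 0.29) and AHNAK (1.82 ± 0.20). The ribosomal RNA precursors RNA45SN2 (2.99 ± 0.30), RNA45SN1 (2.85 ± 0.37) and RNA45SN4 (2.45 ± 0.28), made in the nucleolus and also chosen after their values were seen, were higher in nuclei.

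On the cytoplasmic side of control cells stood RNR2 (-3.21 ± 0.44) and RNR1 (-3.20 ± 0.47) and several messenger RNAs. These were the ferritin heavy chain FTH1 (-1.81 ± 0.28), cyclin I CCNI (-1.75 ± 0.22), NTAN1 (-1.67 ± 0.25), ERG28 of sterol synthesis (-1.49 ± 0.25), the ATP synthase subunit ATP5PF (-1.48 ± 0.23), WSB2 (-1.47 ± 0.21), ERGIC1 (-1.43 ± 0.24) and FHL1 (-1.29 ± 0.22). The microRNA gene MIR6784 (10.9 and 41.4 FPKM) and SNORA80E (7.55 and 4.79 FPKM) were detected in cytoplasm and listed at 0 in both nuclei. Of the 38 calls tested with each of the 4 libraries left out, 10 held throughout, namely SNAR-C4, SNORA63B, SCARNA9, SNAR-B1, SNORA24, SNORA80E, IQGAP1, ANLN, DBN1 and RNA45SN2. Of the others 25 ended without control cytoplasmic 2 (adjusted p = 0.0530 to 0.277 in limma), 22 without control nuclear 3 (0.0677 to 0.302) and 20 without control nuclear 2 (0.0519 to 0.169). The number of genes was 52, 25 and 30 without control nuclear 2, control nuclear 3 and control cytoplasmic 2, and 1208 without control cytoplasmic 3. It was 134 under quantile normalization, 49 with mitochondrial genes removed, 26 in a fit on the compared groups alone, 144 with the number as a block, 44 with a block within condition and 37 with voom on recovered reads. Libraries did not overlap for 5394 genes (39.6%, against 33.3% given by chance for exchangeable libraries), and 2383 had an unadjusted p under 0.05.

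Of the lists in control cells, 5 leaned to the nucleus and 3 to the cytoplasm. ER folding and translocation mRNAs were higher in nuclei in 26 of 31 members (median 0.61, camera adjusted p = 5.02e-07, and adjusted p = 0.699 with an estimated correlation), with HSP90B1 (1.82 ± 0.30) and CANX (1.68 ± 0.27) past the threshold over all genes and 8 members adjusted over the list alone. The G2/M genes were higher in 31 of 43 (median 0.42, adjusted p = 0.000365, and adjusted p = 0.699 with an estimated correlation), with ANLN past the threshold and 5 adjusted over the list alone. Detained-intron mRNAs, which encode kinases and splicing factors, were higher in 19 of 25 (median 0.33, adjusted p = 0.00175, and adjusted p = 0.822 with an estimated correlation), with 2 passing adjusted over the list alone and PRPF4B at 1.26 ± 0.28 and OGT at 0.82 ± 0.20. Nucleoporins (24 of 29, median 0.35, adjusted p = 0.00175, and adjusted p = 0.822 with an estimated correlation), with RANBP2 at 1.70 ± 0.44, and cholesterol genes (17 of 24, median 0.27, adjusted p = 0.0381, and adjusted p = 0.699 with an estimated correlation), of which 2 members passed adjusted over the list alone, were the other 2. Ribosomal proteins were lower in nuclei in 79 of 80 (median -0.40, adjusted p = 1.45e-09, and adjusted p = 0.822 with an estimated correlation), with RPS12 at -1.36 ± 0.32. The snoRNA host genes (16 of 20, median -0.53, adjusted p = 0.00175, and adjusted p = 0.822 with an estimated correlation), with SNHG6 at -1.32 ± 0.38, and the respiratory chain (55 of 72, median -0.26, adjusted p = 0.00175, and adjusted p = 0.827 with an estimated correlation) were also lower. Removing mitochondrial genes, with every library rescaled to the same FPKM sum, moved the median of all genes by 0.17 toward the nucleus. It moved those of ribosomal proteins and the respiratory chain to -0.18 and -0.03, against -0.08 and -0.05 under quantile normalization. Among 10000 lists matched on GC content, length and level, a comparison chosen after the data were seen, the respiratory chain lay at percentile 51.5 (matched median -0.26). On length and level alone it lay at percentile 76.07 (matched median -0.30).

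The ER, G2/M and detained-intron calls in control cells held in every omission of a library. The nucleoporin (adjusted p = 0.202), snoRNA host (0.567) and cholesterol (0.318) calls ended without control nuclear 2, the cholesterol call also without control cytoplasmic 3 (0.292), and the ribosomal protein call without control cytoplasmic 2 (0.284), where the direction of the respiratory chain turned (0.361). Quantile normalization ended the ribosomal protein (0.392), respiratory (0.794) and snoRNA host (0.1) calls, and without both nuclear libraries numbered 2, chosen after the data were seen, the nucleoporin (0.214), snoRNA host (0.566) and cholesterol (0.352) calls ended.

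**Figure D3:**
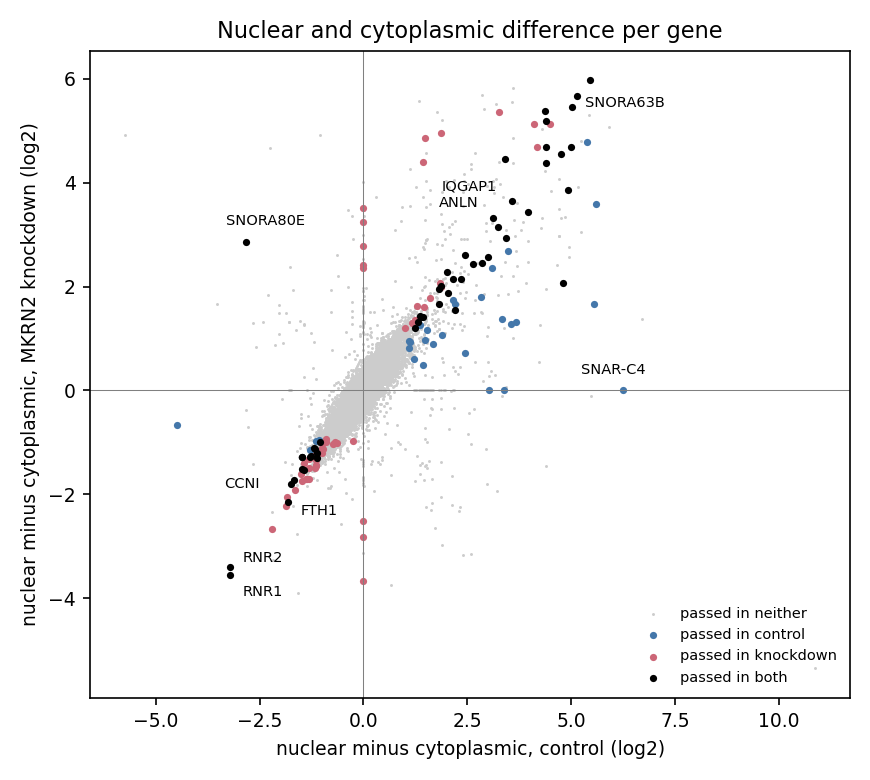
Nuclear minus cytoplasmic difference of each of the 13628 genes in log2(FPKM + 1), in control cells (horizontal axis) and in knockdown cells (vertical axis), coloured by the comparison in which the gene passed. Of the genes that passed in both, 34 lie on the nuclear side in both, 16 on the cytoplasmic side in both, and 1, SNORA80E, on opposite sides.

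In knockdown cells 56 genes were higher in the nucleus and 47 in the cytoplasm, with 28 small RNAs among them. Nuclear snoRNAs and microRNA genes listed at 0 in both cytoplasmic libraries were SNORD14D, SNORA7A, SNORA63B (34.2 and 53.9 FPKM in nuclei), SNORD50A, SNORD77, SNORD5, SNORD4B, SNORD26, SNORD45B, SNORA3B, MIR6859-3 and MIR6797. IQGAP1 (3.65 ± 0.32), ANLN (3.33 ± 0.29), SPTBN1 (3.14 ± 0.41), DBN1 (2.93 ± 0.40), CALD1 (2.29 ± 0.29), SYNE2 (2.01 ± 0.29), AHNAK (1.96 ± 0.20) and MACF1 (1.88 ± 0.32) were again higher in nuclei, as were RNA45SN4 (2.60 ± 0.28), RNA45SN2 (2.56 ± 0.30) and RNA45SN1 (2.45 ± 0.37). On the cytoplasmic side were RNR1 (-3.55 ± 0.47), RNR2 (-3.39 ± 0.44), PPDPF (-2.67 ± 0.48), the ferritin chains FTL (-2.24 ± 0.36) and FTH1 (-2.15 ± 0.28), SH3BGRL3 (-2.06 ± 0.37), the translation repressor EIF4EBP1 (-1.91 ± 0.34), CCNI (-1.79 ± 0.22), MYL6B (-1.75 ± 0.31) and NTAN1 (-1.72 ± 0.25). MIR4322 and SCARNA23 were detected in knockdown cytoplasm alone. Of 39 calls tested with each of the 4 libraries left out, 10 held throughout, namely IQGAP1, ANLN, AHNAK, SNORA63B, SNORD50A, SNORD77, SNORD26, MIR4322, SCARNA23 and RNA45SN4. Of the others 28 ended without MKRN2 knockdown cytoplasmic 3 (adjusted p = 0.0530 to 0.176 in limma), 27 without MKRN2 knockdown cytoplasmic 2 (0.0638 to 0.311), 23 without MKRN2 knockdown nuclear 2 (0.0510 to 0.205) and 12 without MKRN2 knockdown nuclear 3 (0.0530 to 0.0975). The number of genes was 40, 152, 26 and 29 without MKRN2 knockdown nuclear 2, nuclear 3, cytoplasmic 2 and cytoplasmic 3. It was 40 with no filter on low values, 50 with mitochondrial genes removed, 66 in a fit on the compared groups alone, 166 with the number as a block, 41 with a block within condition and 41 with voom on recovered reads. Libraries did not overlap for 6343 genes (46.5%, against 33.3% given by chance for exchangeable libraries), and 3032 had an unadjusted p under 0.05.

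The 4 nuclear lists of knockdown cells were G2/M genes (31 of 43, median 0.60, camera adjusted p = 1.65e-05), ER genes (25 of 31, median 0.41, adjusted p = 0.00143), detained-intron mRNAs (19 of 25, median 0.34, adjusted p = 0.00143) and nucleoporins (23 of 29, median 0.27, adjusted p = 0.00300). The 4 cytoplasmic lists were ribosomal proteins (79 of 80, median -0.64, adjusted p = 3.02e-15), the respiratory chain (60 of 72, median -0.37, adjusted p = 1.65e-05), snoRNA host genes (15 of 20, median -0.63, adjusted p = 0.00300) and histones (27 of 32, median -0.33, adjusted p = 0.00595). For each of the 8 the adjusted p was 0.647 with an estimated correlation. ANLN, the checkpoint kinase BUB1 (1.35 ± 0.23), HSP90B1 (1.66 ± 0.30) and ATP5PF (-1.29 ± 0.23) passed over all genes, and adjusted over the list alone 17 G2/M, 6 ER, 5 detained-intron and 3 snoRNA host genes passed. With mitochondrial genes removed and every library rescaled to the same FPKM sum, the median of all genes moved by 0.32 toward the nucleus. The medians of the respiratory chain, ribosomal proteins and histones moved to 0.05, -0.22 and -0.00873 (-0.04, -0.09 and -0.39 under quantile normalization). Among lists matched as before the respiratory chain lay at percentile 43.13 (matched median -0.35), nucleoporins at 95.97 and detained-intron mRNAs at 96.14. On length and level alone the respiratory chain lay at percentile 94.17 (matched median -0.47). The G2/M and detained-intron calls held in every omission of a library, while without MKRN2 knockdown nuclear 2 the calls of nucleoporins (adjusted p = 0.315), snoRNA host genes (0.478), ER genes (0.0744) and histones (0.322) ended, the last also without MKRN2 knockdown cytoplasmic 2 (0.230). Quantile normalization ended the ribosomal (0.0918), respiratory (0.536) and snoRNA host (0.202) calls, and without both nuclear libraries numbered 2 those of nucleoporins (0.493), snoRNA host genes (0.712), ER genes (0.0803) and histones (0.413) ended.

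More transcripts were called the same way in both conditions than independent calls would give. Both comparisons called 34 genes higher in the nucleus, against 0.242 expected from independent calls, and 16 higher in the cytoplasm, against 0.0724 expected. The calls are not independent, since both comparisons shared 1 variance estimate per gene. Libraries of 1 number also deviated together across conditions (r = 0.625 in nuclei and 0.503 in cytoplasm), which can raise the overlap and the correlation below. Across the 13628 genes the nuclear minus cytoplasmic differences of control and knockdown cells, which share no library, correlated with Pearson's r = 0.738, over genes that are not independent replicates. IQGAP1, ANLN, SNORA63B, RNR1, RNR2, FTH1 and CCNI were among the genes called the same way in both.

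**Figure D4:**
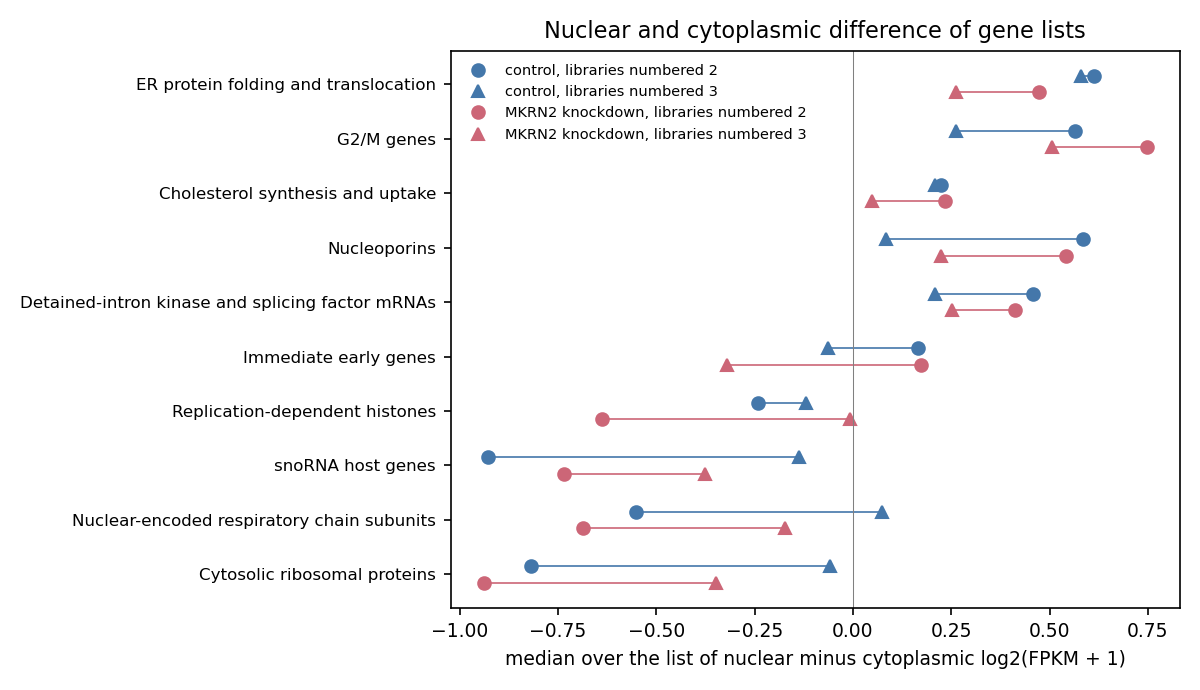
Median nuclear minus cytoplasmic difference in log2(FPKM + 1) of 10 gene lists (vertical axis) for the pairs of libraries numbered 2 (circles) and 3 (triangles), in control and in knockdown cells. Ribosomal protein mRNAs lie at -0.82 and -0.06 in control and at -0.94 and -0.35 in knockdown cells, and ER mRNAs at 0.61 and 0.58 in control and at 0.47 and 0.26 in knockdown cells.

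A further comparison asked which mixture of the nuclear and cytoplasmic profiles came closest to the total RNA profile. The nuclear weight is not a measured share of RNA, because the total libraries did not lie between the fractions. On the first principal component they lay at -47.0 to -38.5, nuclear libraries at -33.8 to 20.4 and cytoplasmic ones at 24.5 to 76.3. Across genes, the total level minus that of the fractions rose with transcript length (Spearman's rho = 0.550). The nuclear weight was 68.8% ± 32.0 (SD, n = 2) in control and 82.1% ± 15.6 in knockdown cells. The single values were 91.4% and 46.2% in control and 93.2% and 71.1% in knockdown cells, each from libraries of 1 number. With total libraries of 1 number set against the fractions of the other, they were 60.5% and 90.6% in control and 80.1% and 94.1% in knockdown cells. Both ways, the higher weight of a condition went with the fraction libraries numbered 2. The difference of 13.4 percentage points was smaller than the spread between replicates (exact two-sided permutation test, p = 0.667, smallest possible p 0.333), and without the control value of libraries numbered 3 it was -9.22.

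The remaining lists passed in none of the 6 comparisons. For GLE1 and mRNA export factors (34 measured) the median change in ratio was -0.05 (adjusted p = 0.620), with the export factor THOC1 at 0.35 ± 0.31. The interferon response (20 measured) had a median of 0.09 in total RNA (adjusted p = 0.0665) and p53 targets (23 measured) one of 0.01 (adjusted p = 0.583), with the death receptor FAS at 0.39 ± 0.29. Proteasome subunits (31 measured) had a median of -0.05 (adjusted p = 0.101), heat shock proteins (19 measured) 0.04 (adjusted p = 0.615), ATF4 and the integrated stress response (25 measured) 0.03 (adjusted p = 0.233), and G1/S genes (36 measured) 0.02 (adjusted p = 0.719), each in total RNA. Markers of other cell types had 5 measured members and a median of -0.06 in total RNA (adjusted p = 0.582). The 2 measured mitochondrially encoded genes, RNR1 and RNR2, were too few for the test, and both differed by 0.14 in total RNA.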

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

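The tests of the separation of nucleus and cytoplasm and of the spread between libraries, the removal of the GC and length trend and the term for the number in each fraction were chosen after the result was seen. The knockdown difference in nuclear RNA differed from that in cytoplasmic RNA, tested as the difference itself, for 11 genes and 5 gene lists. The genes, with the adjusted p of that difference in limma, were SNAR-C4 (7.80e-05), SNORA80E (0.000325), MIR639 (0.00136), MIR6132 (0.00156), CELSR3-AS1 (0.00202), MIR3621 (0.00272), SCARNA23 (0.00350), SNORA49 (0.00559), MIR1289-1 (0.00589), MIR4477B (0.0116) and SNORA29 (0.0116). All 11 are listed at 0 in both libraries of at least 1 of the 4 groups compared. The lists, with the median log2 change in ratio, were cytosolic ribosomal proteins (-0.25), ER protein folding and translocation (-0.31), nuclear-encoded respiratory chain subunits (-0.16), G2/M genes (0.14) and immediate early genes (-0.15), and with an estimated correlation none of the 5 passed (adjusted p = 0.879 to 0.890).

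The first pattern is that 18 of the 19 genes called in the knockdown comparisons and the change in ratio are small RNAs. Of the 19 genes, 11 are above 0 in 2 libraries only, 8 of these at equal reads (tolerance 3%). Among all 89 kept genes above 0 in exactly 2 libraries, 12.4% (95% exact interval 6.33% to 21.04%) had both in 1 group, against 9.09% given by chance, so reads that fall in 1 group by chance may account for the calls of these genes. Whether that covers SNAR-C4 stays open. It measured 58.4 and 96.5 FPKM, with 2.25 times as many reads in 1 library as in the other. FPKM alone does not give its exact number of reads. If reads are whole, a ratio of 2.25 needs several in each library, whereas the 8 genes at equal reads could have as little as 1. The other 8 genes lie outside that test, among them SNORD12B and SNORD26, each above 0 in 10 libraries, and SNORA29, above 0 in 6. A change by the knockdown in more than 1 fraction stays open, because only 7 of the 18 small RNAs differed in at least 2 fractions, and 4 of these 7 had the same sign in each.

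The second pattern is the shift of the 5 lists between nucleus and cytoplasm. The median changes in ratio were set against lists of genes matched on GC content, length and level. They lay at percentile 0 for ribosomal proteins, 0 for ER genes and 0.44 for the respiratory chain. That argues against a trend with GC content and length as the whole cause for these 3. With that trend removed the medians were -0.20, -0.26 and -0.16, and all 3 passed at the preset correlation. A trend with level stays open, because level was matched only in coarse classes and was not removed. Under quantile normalization the ribosomal and respiratory medians were -0.05 and -0.00985, and both calls ended (camera adjusted p = 0.198 and 0.435). The ER genes stood at -0.16 and kept theirs. The matched genes were drawn independently, so the percentiles do not allow for genes of a list that vary together. Immediate early genes lay at percentile 30.74, where the trend with GC content and length could account for them. It stays open for G2/M genes, at percentile 99.98, because with the trend removed their median fell from 0.14 (quartiles -0.06 and 0.30) to 0.03 (-0.05 and 0.14) and the call ended for that reason (adjusted p = 0.131). A sharper separation of the fractions in the knockdown samples stays open, since of 507 genes outside the lists that lay at least 2-fold apart between fractions 68.4% were further apart in knockdown, but 36.1% and 80.9% of the cytoplasmic ones in the numbers 2 and 3, and 55.7% and 52.1% of the nuclear ones, and the ER list, which lies on the nuclear side, runs against it (median 0.61 in control and 0.41 in knockdown), although not with mitochondrial genes removed (0.77 and 0.82). The spread between libraries and an effect of the knockdown itself stay open too, since with a term for the number in each fraction all 5 lists passed at the preset correlation (adjusted p = 6.22e-07 to 0.0101) and none with an estimated one (0.645 each), and leaving out 1 number of 1 fraction, which gives 4 distinct omissions, then ended the call of each of the 5 lists in 2 and turned no direction.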

How the results depend on the processing

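The tests without small RNAs, with the number as a block within fraction, with voom on recovered reads, without both nuclear libraries numbered 2, with the GC and length trend removed, and the omissions for the nuclear weight were chosen after the result was seen. The cause was not tested except where named. Comparisons are in the order total, nuclear, cytoplasmic, ratio, nucleus against cytoplasm in control and in knockdown (8, 10, 6, 11, 80 and 103 genes in limma). Knockdown counts were 5 in total and 6 for the ratio at pseudocount 0.1; 1, 3, 0 (57 at an unadjusted p under 0.05) and 2 at the filter of 5 FPKM, which tests fewer genes; 16, 0 (87) and 0 (90) in a fit on the compared groups, which has fewer degrees of freedom; 1, 0 (60), 1 and 1 without small RNAs; 1, 0 (2033), 1 and 1 without small RNAs and with a block; 1, 0 (64), 0 (43) and 0 (38) with voom, which tests fewer genes; and 13 in cytoplasmic RNA without nuclear 2. With the GC and length trend removed the same 8, 10, 6 and 11 genes passed. Counts for nucleus against cytoplasm were 134 in control under quantile normalization; 49 and 50 without mitochondrial genes, 26 and 66 on compared groups, 144 and 166 with the number as a block, 44 and 41 with a block within condition, and 37 and 41 with voom; and 40 in knockdown with no low filter. Leaving out 1 library gave 8 to 15, 12 to 20, 4 to 9, 10 to 21, 25 to 1208 and 26 to 152 genes. The lone library is then assumed to vary like the other groups.

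The lists called numbered 3, 3, 5, 5, 8 and 8. With an estimated correlation and with fry in 1 direction 0 were called in each comparison, and with fry in either direction 0, 0, 0, 0, 3 and 4. The counts were 5 in total RNA under quantile normalization and with the number as a block, and 6 with a block within fraction; 0 in nuclear RNA with no low filter and under quantile normalization, and 7 with the GC trend removed; 2, 3, 2 and 3 for the ratio with no low filter, under quantile normalization, without nuclear 2 and with the GC trend removed; and 5 and 5 between nucleus and cytoplasm without nuclear 2. Leaving out 1 library gave 1 to 9, 3 to 9, 3 to 7, 0 to 10, 5 to 12 and 5 to 10. Outside the omissions, list results kept their direction and call in 335 cases, 32 of them under median-ratio scaling. They lost the call in 128 and turned in 1, the respiratory chain in knockdown nuclei without nuclear 2 (adjusted p = 0.908). Adjusted p ranged over the omissions, where directions turned, for immediate early genes 0.000925 to 0.614 and glycolysis 0.00411 to 0.814 in nuclei; ribosomal proteins 8.70e-31 to 0.671 and G2/M 0.00308 to 0.994 in cytoplasm; ribosomal proteins 7.87e-21 to 0.896, immediate early 0.00124 to 0.880 and respiratory chain 6.45e-11 to 0.802 for the ratio; and respiratory chain 6.15e-09 to 0.361 in control nucleus against cytoplasm. The respiratory chain in nuclei turned in no omission of 1 library (0.000417 to 0.946).

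Outside the omissions, named genes kept direction and call in 2249 cases, 184 of them under median-ratio scaling. They lost the call in 335, gained it in 23 and turned in 6. These 6 were MKRN1 under quantile normalization (0.00865 nuclear, 0.0468 ratio) and without mitochondrial genes (0.0550 and 0.16), and GLE1 without mitochondrial genes (0.00754 nuclear, 0.14 ratio). Removal of mitochondrial genes with rescaling moved the median of all genes by 0.0949 in nuclear RNA and 0.154 for the ratio. The turns under it therefore go with a shift of all genes. The log2 ranges over the omissions were, for MKRN1, -0.0623 to 0.0118 total, -0.14 to 0.0130 nuclear, -0.26 to 0.19 cytoplasmic and -0.25 to 0.20 ratio; GLE1 -0.41 to 0.20 nuclear, -0.18 to 0.0524 cytoplasmic and -0.35 to 0.26 ratio; in cytoplasm MKRN3 -0.0748 to 0.16, RPL13A -0.10 to 0.91 and NUF2 -0.62 to 0.0722; and for the ratio RPS28 -1.14 to 0.19 and COX6A1 -1.19 to 0.16. MKRN2 itself stayed below control in every omission, at -0.73 to -0.62 in total, -0.71 to -0.44 in nuclear and -1.32 to -0.80 in cytoplasmic RNA. The difference in nuclear weight was 11.6 to 18.4 percentage points under the alternatives and -9.22 to 36.0 over the omissions. The numbers 2 and 3 pair no libraries in the main gene and list tests. Libraries of 1 number are combined in the nuclear weight, the figure of lists, and the naming and non-overlap count for the ratio. They are also combined in the pairs of MALAT1 and NEAT1, the separation test by number and the list medians by number. Deviations of libraries of 1 number correlated across genes at 0.625 between control and knockdown nuclear, 0.503 between the cytoplasmic and 0.209 between the total groups, and at -0.117 to 0.397 between fractions. Depth limits the small RNAs, of which 11 called in the knockdown or ratio comparisons are above 0 in 2 libraries only.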

Other observations

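The tests of transcript GC content against the deviation of single libraries, and the list of cytoskeletal genes, were chosen after the result was seen. The list of secreted and membrane protein genes was also not among the lists fixed before the data were examined. Across 12695 genes, the deviation of the libraries numbered 2 from their groups correlated with the GC content of the transcript. Spearman's rho, over genes that are not independent replicates, was 0.583 in control nuclear, 0.624 in knockdown nuclear, 0.653 in control cytoplasmic and 0.581 in knockdown cytoplasmic RNA, and -0.324 and -0.409 in control and knockdown total RNA. Among genes above the upper quartile of GC content (56.4%) the median log2 difference of number 2 minus number 3 was 0.39, 0.58, 0.59 and 0.34 in the same order of nuclear and cytoplasmic groups, and below the lower quartile (42.05%) it was -0.22, -0.35, -0.45 and -0.35. The knockdown difference correlated with GC content with rho = -0.697 in nuclear, 0.133 in cytoplasmic and -0.233 in total RNA.

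The snoRNA genes, 549 in the table, were above 0 for 252 to 270 genes in total, 179 to 277 in nuclear and 120 to 154 in cytoplasmic libraries, and held 3.28% to 6.55% of the FPKM of a library. RNR1 and RNR2 in nuclei were lower in the libraries numbered 2 than in those numbered 3 in both conditions, at 0.304 to 0.756 times the level.

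A hypothesis was tested for the messenger RNAs high in the nuclear preparation, such as IQGAP1, ANLN and CANX. Transcript length may contribute, since the nuclear minus cytoplasmic difference in control cells rose with length (Spearman's rho across genes 0.350, and 0.426 in knockdown cells), from a median of -0.22 in transcripts up to 2303 nt (lower quartile) to 0.16 in those from 5336 nt (upper quartile). Cytoplasmic libraries of the 2 numbers also differed with length. The deviation of number 2 correlated with length at rho = -0.513 in control and -0.311 in knockdown cytoplasm, against -0.047 and 0.044 in nuclei. In the means over both numbers, length does not account for all of it. The 49 messenger RNAs of cytoskeletal and junction proteins had a median of 0.66 in control and 0.53 in knockdown cells, and the 58 of secreted and membrane proteins, made at the ER, 0.80 and 0.50, each at percentile 100 of 10000 lists matched on length and level, whose medians were 0.12 to 0.15. The cytoskeletal medians were 0.94 in control and 0.93 in knockdown for number 2. For number 3 they were 0.09 (27 of 49 members positive) and 0.20. Those of secreted and membrane proteins were 1.07 and 0.82 for number 2, and 0.61 and 0.22 for number 3. Matched lists were not compared within a single number, so whether length accounts for the values of number 3 was not tested. RNA bound to the cytoskeleton or to the ER that stays with the nuclear pellet is a candidate explanation, and retention inside the nucleus stays open, since no measurement here tells the 2 places apart. In these lists SPTAN1 (3.11 ± 0.52, adjusted p = 0.0398 in limma) passed in control cells and DST (1.99) in knockdown cells.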
